A study of Mus musculus with 9 samples.

How the data were processed

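RNA was measured on 9 Affymetrix MOE430A arrays, on each of which a set of short oligonucleotide probes reports the level of a transcript from biotin-labelled RNA copied from oligo-dT-primed cDNA. The samples were primary mouse megakaryocytes at 4 stages that the labels name MKP (2 arrays), MK3 (2 arrays), MK4 (2 arrays) and MK6 (3 arrays). Each array was placed in its stage from its title. The values used are the deposited probe set intensities of these single-colour arrays on a linear scale, which the authors made with MAS5 per the submitters' processing notes. The version and the settings of MAS5 are not given in the sources used here, and no detection calls were used here.

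The table held 22690 probe sets, of which 64 were control probe sets. The platform annotation paired 20380 probe sets with 1 gene, 691 with several and 1555 with no gene name here. Of the first kind, 20364 were found in the reference gene table, from which their current symbols were taken. Probe sets with several names or none, and the controls, were left out of the gene tests. The deposited arrays did not share a common level. Their trimmed means, with 2% taken off each end, ran from 102 to 221, beyond the tolerance of 10% set for using the values unscaled. Each array was therefore multiplied to a common trimmed mean of 161. Values were taken as log2(signal + 15.2), the pseudocount being the 20th percentile of all scaled values, so a fold on this scale understates the change of dim genes. A probe set was kept if its scaled signal was above 46.7, the 40th percentile, on at least 2 arrays. Of the probe sets of a gene the one with the highest mean was used, which left 9382 of 12393 genes for testing. Scaling to a common level leaves out any change in the total RNA per cell.

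All 9 arrays entered 1 linear model with a mean per stage, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 5 residual degrees of freedom). The comparisons were MK6 against MKP for the whole course, the successive steps MK3 against MKP, MK4 against MK3 and MK6 against MK4, and a moderated F test over the 3 steps. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Errors after ± are standard errors of a difference in this fit unless an SD is named. Comparisons that share arrays are not independent: MK3 enters 2 successive steps, and MKP enters both the first step and the whole course.

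Gene lists were tested as sets with camera at a preset inter-gene correlation of 0.01, with the correlation estimated from the data and with fry as alternatives, and p was adjusted over the 22 lists within a comparison. The lists covered megakaryocyte and platelet receptors and adhesion, alpha-granule cargo and biogenesis, dense-granule machinery, the cytoskeleton of proplatelet formation, megakaryocyte transcription factors, reported NF-E2 target genes, DNA replication and G1/S, mitosis and cytokinesis, ribosome biogenesis, stem and early progenitor genes, mitochondrial respiration, cholesterol synthesis, apoptosis regulators, eicosanoid synthesis, and endoplasmic reticulum folding and stress. Markers of other cells that the cultures could hold made up 7 of the lists: erythroid, neutrophil and granulocyte, monocyte and macrophage, mast cell and basophil, lymphocyte, hepatocyte, and fibroblast and endothelial. A further 8 lists were chosen after the main results were seen: a second hepatocyte list, antioxidant response genes, hypoxia-regulated genes, glycolysis, lysosome, interferon-stimulated genes, proteasome and aminoacyl-tRNA synthetases. Their p was adjusted over these 8 alone, with an adjustment over all 30 lists as a check added later. List members were matched by current symbol, or by an older symbol that is not the current symbol of another gene. That last condition was added after the first list results were seen, because older symbols had matched a few members of the hepatocyte, second hepatocyte and glycolysis lists to other genes.

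The genes named for MK6 against MKP were the 12 largest rises and the 12 largest falls among called genes whose 2 groups of arrays do not overlap, with 6 each way for every successive step. From each list the 4 measured members with the largest absolute MK6 minus MKP difference were added, whether or not they passed, along with Itga2b, Nfe2, Gata1, Pf4, Lims1 and 1 further gene not analysed here. Any other gene named was chosen after its values were seen. The stages, the comparisons, the preparation of the values, the first 22 lists, this naming rule and all alternatives but 2 were chosen before the data were examined.

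The alternatives were 2 other pseudocounts, 2 other filters, 2 other scalings (quantile normalization and a common median), 3 other ways of treating several probe sets of a gene, 3 other variance models, a fit to the arrays of the 2 stages alone, and each array left out in turn. The 2 chosen after seeing the data left out MK6 replicates 2 and 3 together, and added the 3' to 5' beta-actin ratio of each array as a covariate. The fit and list test were run on 10 simulated draws with the real genes' means and spread and 200 of 9382 genes changed in each. For MK6 against MKP, 16.4% of genes changed by 1 log2 unit and 71.3% of those changed by 2 were called, and 5.59% of calls were false. For MK3 against MKP the same shares were 9.70%, 63.0% and 4.08%, for MK4 against MK3 11.0%, 63.8% and 6.38%, and for MK6 against MK4 17.1%, 71.3% and 4.42%. Real shares may differ, and the number of arrays limits every comparison's precision.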

Results

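Gene expression was measured along the maturation of primary mouse megakaryocytes, the marrow cells that release platelets. Marrow or fetal liver cells had been cultured with thrombopoietin, the cytokine that drives this lineage, and sorted on CD41, a surface integrin that marks it, and on forward scatter, which follows cell size. The 4 stages were MKP, MK3, MK4 and MK6, with 2, 2, 2 and 3 arrays. The numbers in the last 3 names match culture days 3, 4 and 6, and the labels give no day for MKP. The labels do not say whether the arrays of a stage came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Across the 9382 tested genes, which are not independent replicates, Pearson's r was 0.835 to 0.968 within a stage (6 pairs) and 0.745 to 0.955 between stages (30 pairs).

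RNA quality differed between stages. The ratio of the 3' to the 5' beta-actin control, which increases as RNA fragments, was 0.957 to 1.09 on the MKP, MK3 and MK4 arrays and 1.33, 3.21 and 1.49 on MK6 replicates 1, 2 and 3. The same ratio for Gapdh, a glycolytic enzyme, was 3.27 on MK6 replicate 2 and 0.805 to 1.13 on the other 8 arrays. MK6 replicates 2 and 3 also had the lowest trimmed means as deposited, 102 and 103, and replicate 3 the highest spike-in controls relative to its trimmed mean (3.25 log2 units, against 1.64 to 2.29 on the others). The leading counts are therefore also given without these 2 arrays, a choice made after seeing the data.

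**Figure D1:**
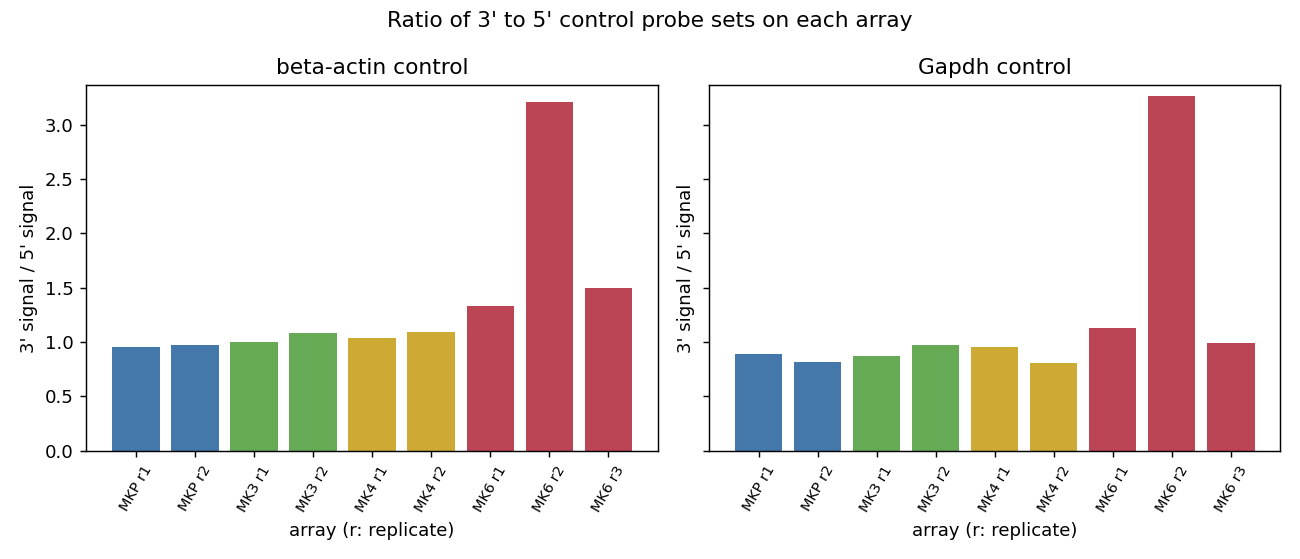
Ratio of the 3' to the 5' signal of the beta-actin and Gapdh control probe sets (y axis, no unit) on each of the 9 arrays (bars, coloured by stage). MK6 replicate 2 stands at 3.21 for beta-actin and 3.27 for Gapdh, and no array of another stage exceeds 1.09 for beta-actin.

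From MKP to MK6, neutrophil markers and genes of the progenitor state were lower as sets by camera (both adjusted p = 0.45 with an estimated correlation), and the genes with the largest rises on the log2 scale used were Mmp12, Fbxo32 and Tesc. The largest rise was that of Mmp12, a secreted metalloelastase best known from macrophages, from a mean log2 signal of 4.56 ± 0.26 (SD, n = 2) to 9.61 ± 0.82 (SD, n = 3). The difference was 5.05 ± 0.62 (adjusted p = 0.004) in limma. Its scaled signals on the MKP arrays were 5.66 and 11.6, below both the filter of 46.7 and the pseudocount of 15.2, so the size of this rise depends on the pseudocount and no fold is given. Fbxo32, a ubiquitin ligase subunit, rose by 4.27 ± 0.52, Tesc, a calcium-binding protein, by 3.90 ± 0.65, and Hilpda, a lipid droplet protein, by 3.54 ± 0.50. Srxn1, which repairs oxidised peroxiredoxins, rose by 3.18 ± 0.35 on the probe set used. Its other probe sets gave -0.078, 1.90 and 1.35, none of them called. Il7r (3.31), the kinase gene Sgk1 (3.14), the creatine transporter Slc6a8 (3.08), Ctnnal1 (3.03), the lipid phosphatase Plpp3 (3.01), Gpr137b-ps (2.92) and the fatty acid receptor Cd36 (2.92) completed the 12 largest rises. The 12 had adjusted p of 0.00271 to 0.0106. Fbxo32 was also below the filter on both MKP arrays. Among the falls below, Ikzf1, Hdc and Rrp9 were so on all 3 MK6 arrays and Elane, Ccr2, Tk1, Gfi1 and B4galnt1 on 2. These sizes are uncertain too, as is the signal of Gpr137b-ps, a pseudogene with a near-identical relative.

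Elane, neutrophil elastase, had the largest fall, from 11.77 ± 0.10 (SD, n = 2) to 6.85 ± 2.13 (SD, n = 3). The difference was -4.92 ± 0.86 (adjusted p = 0.012) in limma. The related granule genes Ctsg (-4.24 ± 0.79), Prtn3 (-3.52 ± 0.68) and Mpo (-3.44 ± 0.82) fell with it. In other settings Elane and these were as small as -2.46, -1.99, -1.62 and -1.14. Gfi1 (-3.19), a repressor that directs granulocyte development, and Hdc (-3.14), which makes histamine, fell too. The chemokine receptor Ccr2 (-3.67), haptoglobin Hp (-3.65), the lymphoid transcription factor Ikzf1 (-3.34), the thymidine kinase Tk1 (-3.26), Chil3 (-3.05) and the ganglioside enzyme B4galnt1 (-3.04) completed the 12 largest falls. In total 259 genes were higher and 276 lower in MK6 (535 of 9382 tested, 480 of them by at least 2-fold). Without MK6 replicates 2 and 3 there were 20 and 29. Of these 49 genes, 47 were among the 535 in the same direction. The counts of higher and lower genes were 3 and 0 without MKP replicate 1, 15 and 6 without MKP replicate 2. They were 561 and 526 without MK6 replicate 1, and 83 and 64 without MK6 replicate 2. Of the 56 called results among the named genes of this comparison, 56 and 52 missed the threshold without MKP replicates 1 and 2, and 5, 31 and 5 without MK6 replicates 1, 2 and 3. Leaving out either MK4 array ended 10 of these calls, and leaving out either MK3 array 1.

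**Figure D2:**
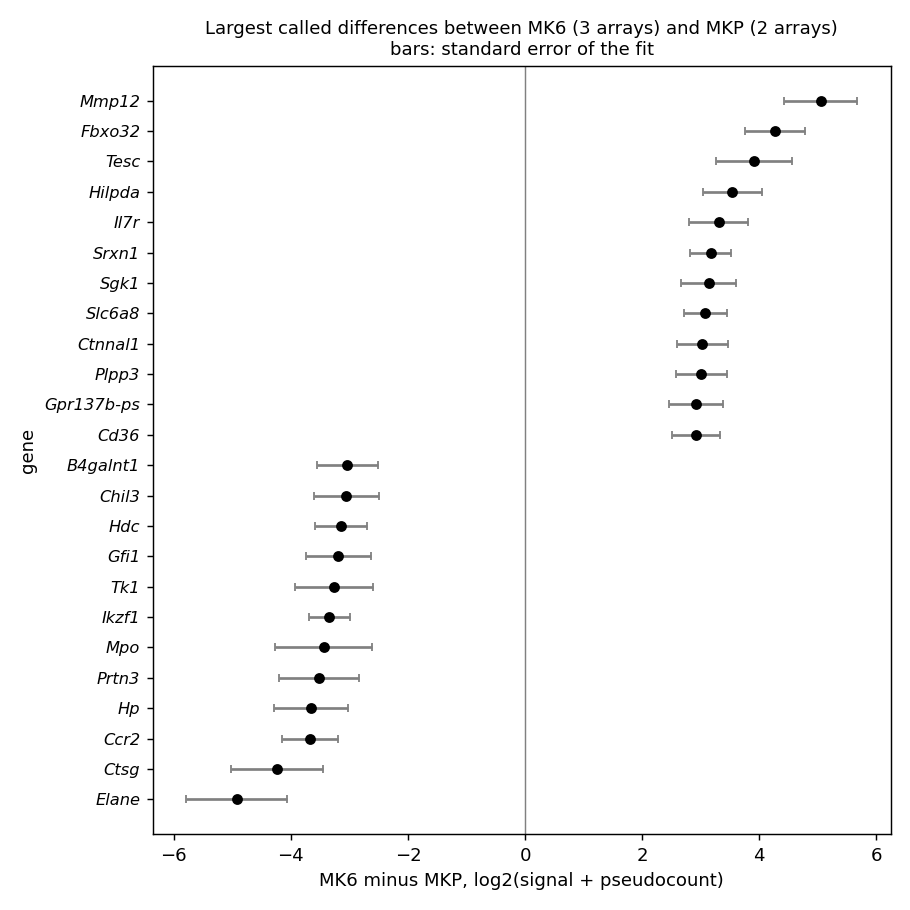
MK6 minus MKP difference in log2(signal + pseudocount) (x axis) of the 12 called genes with the largest rise and the 12 with the largest fall (y axis); bars are standard errors of the fit. Values run from -4.92 for Elane to 5.05 for Mmp12.

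Receptors and reported NF-E2 target genes lay higher as sets in MK6 than in MKP by camera (adjusted p = 0.80 and 0.45 with an estimated correlation), while the cytoskeletal and transcription factor lists had more falls than rises among their called members. Itga2b, the CD41 chain on which the cells were sorted, rose by 1.53 ± 0.38 (adjusted p = 0.0433) in limma. Its partner Itgb3 lay at -2.01 (adjusted p = 0.0568), Cd84 at 1.30 and the junction protein Esam at 1.16, none past the threshold. Of the receptor and adhesion list's 23 measured members, 2 rose and 0 fell (6 and 1 adjusted over the list alone). The median difference was 0.66 (camera adjusted p = 0.0257, adjusted p = 0.80 with an estimated correlation). The call ended without MK6 replicate 1 at 0.63 (adjusted p = 0.28) and with scaling to a common median at 0.53 (adjusted p = 0.0586). Among alpha-granule genes Ctla2a (2.58 ± 0.48), Ecm1 (2.04), the platelet adhesion protein Vwf (1.90) and Sparc (1.82) rose, and the chemokine Pf4 lay at 1.10 (adjusted p = 0.0507). Of that list's 18 measured members, 4 rose and 1 fell (7 and 1 adjusted over the list alone). The median difference was 0.27 (camera adjusted p = 0.19, adjusted p = 0.80 with an estimated correlation). Without MK6 replicate 2 its median was 0.53 (adjusted p = 0.0278), and without MK6 replicates 2 and 3 0.68 (adjusted p = 4.1e-04). It also passed with the stricter filter at 0.66 (adjusted p = 0.0472) and with the beta-actin ratio as a covariate at 0.75 (adjusted p = 0.00144).

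Rab27b, a small GTPase of granule secretion, rose by 1.47 ± 0.36 on the probe set used, with 0.39 (adjusted p = 0.57) on another, and was the only called member among the 14 measured dense-granule genes (1 rose and 0 fell adjusted over the list alone). The median of that list was 0.14 (camera adjusted p = 0.73, adjusted p = 0.80 with an estimated correlation), and Hps1 lay at -1.27, Mlph at 0.90 and Hps4 at 0.84. Rab27b also led the reported NF-E2 targets, with Casp12 at 1.41, the thromboxane synthase Tbxas1 at 1.20 and Lims1 at 0.61, for which another probe set gave -0.22. That list of 4 measured genes, 1 of which rose (3 adjusted over the list alone), was shifted up (median 1.30, camera adjusted p = 0.0151, adjusted p = 0.45 with an estimated correlation). This call ended without MK6 replicate 1 at 1.16 (adjusted p = 0.12). Among cytoskeletal genes the tubulin Tubb2a rose by 1.66, while the actin regulators Pfn1 (-2.31) and Was (-1.02) and the integrin linker Tln1 (-1.45, 0.81 on another probe set) fell. Of the 25 measured members, 1 rose and 3 fell (3 and 5 adjusted over the list alone). The median was 0.14 and the mean -0.023, and the camera direction was down (adjusted p = 0.73, adjusted p = 0.93 with an estimated correlation).

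Nfe2 and Gata1, central transcription factors of the lineage, lay at 0.088 ± 0.42 (adjusted p = 0.91) and 0.37 ± 0.35 (adjusted p = 0.53) in limma. Myb, which maintains progenitors, fell by 3.01 ± 0.58 log2 units, and the cofactor Ldb1 (-1.35) and the repressor Etv6 (-0.82) also fell, whereas Runx1 lay at -0.90 (adjusted p = 0.0763). Of the 21 measured members, 0 rose and 3 fell (1 and 5 adjusted over the list alone). Here the median was 0.088, the mean -0.19 and the camera direction down (adjusted p = 0.21, adjusted p = 0.71 with an estimated correlation). Several of these calls were close to the threshold. That of Itga2b ended without any 1 of MKP replicate 1, MKP replicate 2, MK4 replicate 1, MK4 replicate 2, MK6 replicate 1, MK6 replicate 2 and MK6 replicate 3 (adjusted p 0.0121 to 0.30 over the 9 arrays left out), and that of Etv6 without any 1 of MKP replicate 1, MKP replicate 2, MK3 replicate 1, MK3 replicate 2, MK4 replicate 1, MK4 replicate 2 and MK6 replicate 2 (0.042 to 0.33). Those of Vwf, Rab27b and Pfn1 each ended in 6 of the 9 cases.

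As sets, the DNA replication, mitosis, ribosome biogenesis and stem and progenitor lists were lower in MK6 by camera (adjusted p = 0.45, 0.51, 0.45 and 0.45 with an estimated correlation). Of their members 5 of 26, 1 of 28, 4 of 19 and 4 of 14 fell, and the mitosis call ended without MK6 replicates 2 and 3. Tk1, Mcm3, a subunit of the replicative helicase (-2.22 ± 0.36, with 0.31 on 1 of its other probe sets), and Rrm1, a subunit of ribonucleotide reductase (-1.95 ± 0.29), fell, and Mcm5 lay at -2.09 (adjusted p = 0.0546). Of the DNA replication and G1/S list's 26 measured members, 0 rose and 5 fell (0 and 21 adjusted over the list alone). All 26 differences were negative (median -1.14, camera adjusted p = 5.6e-13, adjusted p = 0.45 with an estimated correlation). The median was -0.74 (adjusted p = 7.6e-11) without MK6 replicate 3 and -0.61 (adjusted p = 7.4e-09) without MK6 replicates 2 and 3. Of the mitosis and cytokinesis list's 28 measured members, 0 rose and 1 fell (0 and 5 adjusted over the list alone). Birc5 lay at -1.997, Bub1b at -1.88, Ccna2 at -1.85 and Ect2 at -1.68, none past the threshold. The median was -0.94 (camera adjusted p = 2.4e-08, adjusted p = 0.51 with an estimated correlation). It was -0.44 (adjusted p = 6.4e-05) without MK6 replicate 3 and -0.17 (adjusted p = 0.11) without MK6 replicates 2 and 3, which ended the call.

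Among ribosome biogenesis genes Rrp9 (-2.22), Nolc1 (-1.50) and the RNA methyltransferase gene Fbl (-1.44) fell and Nop58 lay at -1.59. Of the list's 19 measured members, 0 rose and 4 fell (0 and 10 adjusted over the list alone). All 19 differences were negative here too (median -0.86, camera adjusted p = 2.4e-08, adjusted p = 0.45 with an estimated correlation). Besides Myb, the stem and progenitor genes Myc (-2.19), the stem cell factor receptor Kit (-1.64) and Cd34 (-1.49) fell, as 4 of 14 measured members did (5 adjusted over the list alone). That list had a median of -0.32 (camera adjusted p = 0.00371, adjusted p = 0.45 with an estimated correlation), and of -0.48 (adjusted p = 0.00457) without MK6 replicate 3. Actin ratios were highest in MK6, so a covariate cannot separate RNA quality from stage. On MK6 replicates 1, 2 and 3, with ratios of 1.33, 3.21 and 1.49, the mean log2 signal was 8.05, 7.78 and 6.58 for DNA replication, 8.18, 7.61 and 6.43 for mitosis, 8.09, 8.10 and 7.50 for ribosome biogenesis and 7.91, 7.76 and 7.30 for stem and progenitor genes. With the ratio as a covariate the 4 medians were -1.45 (adjusted p = 3.7e-15), -0.85 (adjusted p = 6.8e-07), -1.22 (adjusted p = 7.9e-10) and -0.43 (adjusted p = 0.00161).

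The cholesterol synthesis list was lower as a set in MK6 by camera (adjusted p = 0.51 with an estimated correlation). Fdps, which makes farnesyl diphosphate, fell by 2.87 ± 0.53 log2 units, and Msmo1 (-1.95), Cyp51 (-1.35) and Hmgcs1 (-1.30) did not pass the threshold. Of the list's 15 measured members, 0 rose and 2 fell (0 and 4 adjusted over the list alone). Their median was -0.91 (camera adjusted p = 7.0e-05, adjusted p = 0.51 with an estimated correlation), and -0.60 (adjusted p = 6.8e-04) without MKP replicate 1 and -0.37 (adjusted p = 0.0486) without MK6 replicates 2 and 3. Ddit3, a transcription factor of the endoplasmic reticulum stress response, rose by 1.47, the chaperone gene Hsp90b1 fell (-1.19), and Pdia3 (-1.17) and Manf (-0.97) did not pass. Of that list's 15 measured members, 1 rose and 1 fell (1 and 4 adjusted over the list alone). As a set they had a median of -0.43 (camera adjusted p = 0.0309, adjusted p = 0.45 with an estimated correlation). Its call ended without MKP replicate 2 at -0.43 (adjusted p = 0.0551), without MK6 replicate 2 at -0.37 (adjusted p = 0.0575) and with a common median at -0.55 (adjusted p = 0.0586). It also ended without MK6 replicates 2 and 3 at -0.39 (adjusted p = 0.20) and with the beta-actin ratio as a covariate at -0.22 (adjusted p = 0.20).

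Mitochondrial respiration genes had 0 rises and 0 falls among 19 members in limma, with 0 and 0 adjusted over the list alone. Their median was -0.094 (camera adjusted p = 0.10, adjusted p = 0.80 with an estimated correlation), with Idh3a at -0.74, Uqcrc1 at -0.68, Cs at -0.50 and Atp5a1 at -0.46. Without MKP replicate 2, MK6 replicate 1 or MK6 replicate 2 this list passed, at -0.29 (adjusted p = 0.0435), -0.20 (adjusted p = 0.0277) and -0.25 (adjusted p = 0.0141). It also passed with no filter on low values at -0.094 (adjusted p = 0.0341) and with the beta-actin ratio as a covariate at -0.42 (adjusted p = 0.00418). Among apoptosis regulators the initiator caspase Casp8 fell (-1.12) and the inhibitor Birc2 rose (0.95), with Bak1 at -0.94 and Bid at -0.79 on the probe sets used. Their other probe sets gave -2.42 (adjusted p = 0.0145) and -2.43 (adjusted p = 0.0125), adjusted over probe sets, which passed. Of the 14 measured members, 1 rose and 1 fell (1 and 3 adjusted over the list alone). These had a median of 0.12, a mean of 0.0076 and a camera direction of down (adjusted p = 0.73, adjusted p = 0.83 with an estimated correlation). Of the eicosanoid synthesis list's 9 measured members, 0 rose and 0 fell (1 and 1 adjusted over the list alone). Pla2g4a lay at 1.16, Lta4h at -1.002 and Ptgs2 at -0.69, and the list's median was 0.29 (camera adjusted p = 0.77, adjusted p = 0.84 with an estimated correlation).

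Among markers of other cell types, the neutrophil list was lower as a set in MK6 than in MKP by camera (adjusted p = 0.45 with an estimated correlation). So was the hepatocyte list (adjusted p = 0.51 with an estimated correlation), whereas a second hepatocyte list, chosen after the main results were seen, was not called. Besides Elane, Ctsg, Prtn3, Mpo and Gfi1, 7 of 14 measured neutrophil members fell in all (11 adjusted over the list alone). The median was -2.14 (camera adjusted p = 4.8e-10, adjusted p = 0.45 with an estimated correlation). The list's mean log2 signal was 11.04 ± 0.16 on the MKP arrays (SD, n = 2) and 10.003, 7.73 and 8.37 on MK6 replicates 1, 2 and 3. Without MK6 replicates 2 and 3 the median difference was -0.999 (adjusted p = 3.8e-08). Macrophage markers split, as the scavenger receptor homologue Cd68 (2.003) and the protease Ctss (1.85) rose while the oxidase subunit Cybb (-2.22) and the integrin Itgam (-1.70) fell. Of the 15 measured members, 2 rose and 2 fell (6 and 4 adjusted over the list alone). They had a median of 0.20, a mean of 0.048 and a camera direction of down (adjusted p = 0.93, adjusted p = 0.96 with an estimated correlation). In the hepatocyte list Afp, alpha-fetoprotein, fell (-2.0001), with Fgb at -1.82, Ttr at -1.30 and Alb at -1.18. On the MK6 arrays Fgb and Ttr were below the pseudocount on all 3 and Afp below the filter on 2 of 3, and on the MKP arrays Fgb and Ttr were below the filter on 1 and 2 of 2, so these sizes are uncertain. Of its 8 measured members, 0 rose and 1 fell (0 and 4 adjusted over the list alone). The median was -0.88 (camera adjusted p = 0.0215, adjusted p = 0.51 with an estimated correlation), a call that ended without MKP replicate 1 at -0.59 (adjusted p = 0.11) and without MK6 replicate 1 at -0.73 (adjusted p = 0.12). The median includes 3 members below the filter on every MKP and MK6 array, and the other 5 had a median of -1.18. The second hepatocyte list had a median of 0.032 and a mean of -0.12 with camera down (adjusted p = 0.56, adjusted p = 0.86 with an estimated correlation), 9 differences being positive and 7 negative. Its median was 0.37, -0.17 and -0.15 without MK6 replicates 1, 2 and 3 and -0.11 under quantile normalization, with no call.

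Of the remaining marker lists none passed camera with no setting changed. Of the mast cell and basophil list's 8 measured members, 0 rose and 1 fell (1 and 1 adjusted over the list alone), Hdc being the faller. Fcer1a lay at 1.34, Mcpt8 at -0.95 and Cpa3 at -0.78, and the list's median was -0.033 (camera adjusted p = 0.38, adjusted p = 0.80 with an estimated correlation). With the stricter filter it was -0.78 (adjusted p = 0.0472), past the threshold. The collagen gene Col1a2 rose by 1.02 among 7 fibroblast and endothelial genes (1 rose and 0 fell adjusted over the list alone). Dcn lay at -0.70, Col1a1 at 0.60 and Fn1 at -0.59, and the median was 0.31 (camera adjusted p = 0.58, adjusted p = 0.83 with an estimated correlation). Of the erythroid list's 6 measured members, 0 rose and 0 fell (1 and 0 adjusted over the list alone). The globin Hba-a1 lay at 1.30, Epor at 0.58, Klf1 at -0.58 and Hemgn at -0.32. The list's median was -0.21 and its mean 0.096, with camera down (adjusted p = 0.95, adjusted p = 0.96 with an estimated correlation). Of the lymphocyte list's 5 measured members, 0 rose and 0 fell (1 and 1 adjusted over the list alone). Ms4a1 lay at 1.33, Cd79b at -1.21, Ighm at 0.82 and Igll1 at 0.57, and the median was 0.57 (camera adjusted p = 0.73, adjusted p = 0.84 with an estimated correlation).

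Of the 22 lists, 10 passed camera at the preset correlation in this comparison, 2 up and 8 down, and 9, 8 and 11 did in the 3 successive steps. With an estimated correlation 0 passed in any comparison, the smallest adjusted p being 0.17, and fry also called 0, with a smallest adjusted p of 0.054. The median difference of all tested genes between MK6 and MKP was 0.125 log2 units under the scaling used, 0.1001 under quantile normalization and 0.00502 under a common median, against which the values above can be read. The receptor list missed the camera threshold at 0.54 (adjusted p = 0.19) with array weights. Stem and progenitor genes had a median of -0.58 (adjusted p = 5.2e-04) with the mean of a gene's probe sets and -0.49 (adjusted p = 0.00275) without MK6 replicates 2 and 3. Endoplasmic reticulum genes missed the camera threshold at -0.43 (adjusted p = 0.0979) with the stricter filter and -0.13 (adjusted p = 0.16) with the mean of a gene's probe sets. Neutrophil markers had a median of -0.9996 (adjusted p = 0.00418) with the beta-actin ratio as a covariate. Hepatocyte markers missed the camera threshold at -0.58 (adjusted p = 0.10) with the mean of a gene's probe sets, -0.58 (adjusted p = 0.0979) without probe sets shared within or across gene families and -0.91 (adjusted p = 0.0516) with array weights, and had a median of -0.34 (adjusted p = 0.0474) with the higher pseudocount, -1.56 (adjusted p = 0.00847) with the stricter filter and -1.32 (adjusted p = 4.5e-04) without MK6 replicates 2 and 3. No list called in any comparison changed its direction under the other 2 scalings. Of the 41 named genes with several probe sets, 9 had differences of both signs between MK6 and MKP, and none was called both ways. Besides Srxn1, Tln1, Lims1 and Mcm3, these were Atp5a1 (1.05), Idh3a (0.15), Ighm (-0.85 and -0.99), Lta4h (0.39) and Runx1 (0.56), with the value of the other sign in brackets. Called genes with another probe set that did not pass were Ccr2 (-0.74), Col1a2 (0.17), Hsp90b1 (-0.30), Lmna (1.46 in MK3 against MKP), Mcm3 (0.31), Rab27b (0.39), Rrm1 (-1.14), Srxn1 (-0.078, 1.90 and 1.35), Tln1 (0.81) and Ttr (-3.40 in MK4 against MK3). Genes that did not pass but had another probe set that did were Bak1 (-2.42), Bid (-2.43), Cs (-1.34) and Runx1 (-1.33), with p adjusted over probe sets.

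**Figure D3:**
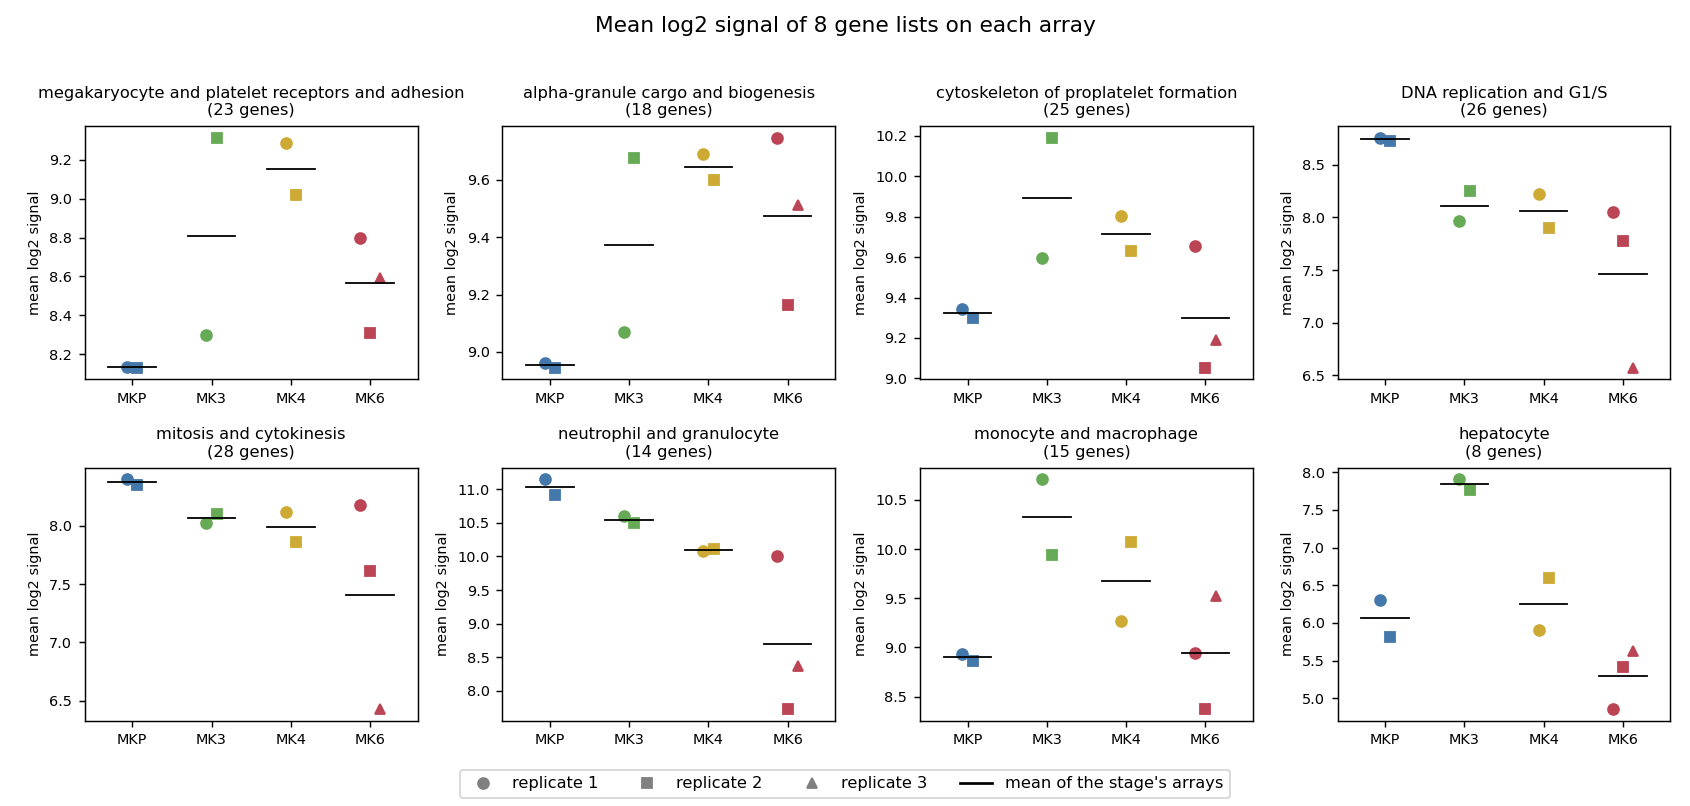
Mean log2 signal (y axis) of the measured members of 8 gene lists on each of the 9 arrays (points, coloured by stage) across the stages (x axis). The hepatocyte markers stand highest at MK3, with a mean of 7.84 against 6.06 at MKP, and the neutrophil markers lowest at MK6, with 8.70 against 11.04 at MKP.

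From MKP to MK3, the step into the day 3 population, 5 genes rose. Lpl, lipoprotein lipase, rose from 8.25 ± 0.022 to 11.73 ± 0.16 (SD, n = 2 each), a difference of 3.48 ± 0.33 (adjusted p = 0.00416) in limma with Benjamini-Hochberg adjustment. Ttr, transthyretin, a liver secretory protein, rose by 3.45 ± 0.38 (adjusted p = 0.00626), and Mrc1, the mannose receptor of macrophages, by 3.06 ± 0.37 (adjusted p = 0.0111). The Ttr signals at MKP were below the filter on both arrays, as they were at MK4. Serpinb6a, an intracellular protease inhibitor, rose by 2.57 ± 0.27 (adjusted p = 0.0052) and Lmna, which encodes lamin A, by 1.95 ± 0.27 (adjusted p = 0.0378). In the other direction 0 genes passed in limma, with 357 lower at an unadjusted p below 0.05, beside 573 higher.

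The macrophage markers lay higher at MK3. Besides Mrc1, C1qc at 2.42, Cd68 at 2.35 and Msr1 at 2.03 had positive differences that did not pass. In all 1 of 15 members rose (11 adjusted over the list alone), and the median was 1.54 (camera adjusted p = 3.0e-10, adjusted p = 0.36 with an estimated correlation). In the hepatocyte list Ttr was joined by Afp at 2.38 and Alb at 2.27. Of 8 members 1 rose (7 adjusted over the list alone), with a median of 1.87 (camera adjusted p = 4.3e-09, adjusted p = 0.18 with an estimated correlation). Neutrophil markers had a median of -0.46 (camera adjusted p = 0.0909, adjusted p = 0.65 with an estimated correlation). They passed without MKP replicate 2 at -0.65 (adjusted p = 0.0391), MK6 replicate 1 at -0.46 (adjusted p = 0.00154), MK6 replicate 2 at -0.46 (adjusted p = 0.0492), or MK6 replicates 2 and 3 (adjusted p = 6.5e-04). They also passed under quantile normalization at -0.47 (adjusted p = 0.043) and a common median at -0.40 (adjusted p = 0.0456). Of the receptor list's 23 measured members, 0 rose and 0 fell (3 and 0 adjusted over the list alone). Their median was 0.58 (camera adjusted p = 4.1e-07, adjusted p = 0.43 with an estimated correlation). The 2 MK3 arrays differed here, since it was 1.19 (adjusted p = 4.5e-20) without MK3 replicate 1 and 0.070 (adjusted p = 0.39) without MK3 replicate 2. The cytoskeletal list (median 0.46, camera adjusted p = 3.8e-06, adjusted p = 0.43 with an estimated correlation) and the alpha-granule list (median 0.42, camera adjusted p = 0.00473, adjusted p = 0.54 with an estimated correlation) were also shifted up, with 2 and 0 rises adjusted over the list alone. Without MK3 replicate 2 these calls ended at 0.17 (adjusted p = 0.0765) and 0.10 (adjusted p = 0.64), and without MK3 replicate 1 the alpha-granule median was 0.66 (adjusted p = 6.0e-07).

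Growth-related lists lay lower at MK3 already. All 26 DNA replication members (median -0.64, camera adjusted p = 2.9e-06, adjusted p = 0.55 with an estimated correlation) and all 19 ribosome biogenesis members (median -0.71, camera adjusted p = 4.3e-09, adjusted p = 0.36 with an estimated correlation) had negative differences. Of these, 0 and 0 passed in limma, and 0 and 1 adjusted over the list alone. Stem and progenitor genes were lower as a set (median -0.60, camera adjusted p = 1.8e-05, adjusted p = 0.17 with an estimated correlation), with 0 called members and 4 adjusted over the list alone. The mitosis list was just past the threshold (median -0.26, camera adjusted p = 0.0451, adjusted p = 0.66 with an estimated correlation). It missed it without MKP replicate 1 at -0.29 (adjusted p = 0.0936), without MK3 replicate 1 at -0.26 (adjusted p = 0.16), without MK3 replicate 2 at -0.35 (adjusted p = 0.0556), and under quantile normalization at -0.27 (adjusted p = 0.0514). The count of 5 higher genes was 0 without MKP replicate 1, MKP replicate 2 or MK3 replicate 1. It was 26 without MK4 replicate 1, 24 without MK4 replicate 2 and 77, with 18 lower, without MK6 replicate 3, as all arrays enter the estimate of the spread. Without MK6 replicates 2 and 3 it was 48, with 10 lower. Lmna missed the threshold without any 1 of MKP replicate 1, MKP replicate 2, MK3 replicate 1, MK3 replicate 2, MK6 replicate 1 and MK6 replicate 2 (adjusted p 0.0143 to 0.52 over the 9 arrays left out). With 1 array left out, camera also called erythroid markers at 0.51 (adjusted p = 0.0391) without MKP replicate 2, NF-E2 targets at 1.10 (adjusted p = 0.00575) without MK3 replicate 1 and cholesterol synthesis at -0.78 (adjusted p = 0.00147), endoplasmic reticulum genes at -0.33 (adjusted p = 0.0209) and mast cell markers at 0.53 (adjusted p = 0.0178) without MK3 replicate 2. Mitosis genes missed the camera threshold at -0.28 (adjusted p = 0.0603) with the lower pseudocount, -0.25 (adjusted p = 0.12) with the stricter filter, -0.25 (adjusted p = 0.0624) with the mean of a gene's probe sets, -0.28 (adjusted p = 0.0569) without probe sets shared within or across gene families, -0.26 (adjusted p = 0.0512) without the intensity trend and -0.30 (adjusted p = 0.0629) with the beta-actin ratio as a covariate. Hepatocyte markers had a median of 1.13 (adjusted p = 5.4e-11) with the higher pseudocount. Other settings in which camera called further lists gave endoplasmic reticulum genes at -0.26 (adjusted p = 0.0146) under quantile normalization, neutrophil markers at -0.43 (adjusted p = 0.0317) with the higher pseudocount, and mast cell markers at 0.84 (adjusted p = 0.0308) with the stricter filter. Median, mean and camera direction differed in sign for transcription factors (0.044, -0.11 and down) and eicosanoid synthesis (-0.017, 0.14 and up), none of them called with no setting changed.

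From MK3 to MK4 the hepatocyte and macrophage markers lay lower again. Ttr was the only called gene, falling from 9.15 ± 0.39 to 5.43 ± 0.49 (SD, n = 2 each), by 3.72 ± 0.38 (adjusted p = 0.00901) log2 units in limma with Benjamini-Hochberg adjustment. In the hepatocyte list 1 of 8 members fell (5 adjusted over the list alone). The median was -1.75 (camera adjusted p = 3.2e-12, adjusted p = 0.17 with an estimated correlation), with Alb at -2.23 and Afp at -2.12. Macrophage markers had a median of -0.79 (camera adjusted p = 1.0e-06, adjusted p = 0.54 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Without MK4 replicate 1 that median was -0.23 (adjusted p = 0.0555), and without MK3 replicate 1 -0.29 (adjusted p = 0.0346). The 2 MK3 arrays enter this step and the one before it with opposite sign, so opposite movements in the 2 steps are not independent. In limma 0 genes were higher, and at an unadjusted p below 0.05 143 were higher and 195 lower. The call of Ttr ended without either MK3 array or either MK4 array, where 0 genes were lower, and without MK3 replicate 2 there was 1 higher gene. Without MK6 replicates 2 and 3 there were 1 higher and 3 lower.

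Among the other lists of this step, endoplasmic reticulum folding genes were shifted up (median 0.38, camera adjusted p = 1.4e-04, adjusted p = 0.25 with an estimated correlation). Of 15 differences 13 were positive, among them Ddit3 at 0.72 and the chaperone gene Hspa5 at 0.45. The receptor list was shifted up (median 0.31, camera adjusted p = 0.0138, adjusted p = 0.70 with an estimated correlation). Its median was -0.18 (adjusted p = 0.0238) without MK3 replicate 1, which turned it, and 0.97 (adjusted p = 1.3e-10) without MK3 replicate 2. It was 0.19 (adjusted p = 0.12) without MK4 replicate 1 and 0.58 (adjusted p = 0.00433) without MK4 replicate 2. Reported NF-E2 targets were shifted up (median 0.71, camera adjusted p = 0.0118, adjusted p = 0.53 with an estimated correlation). The median was 0.13 (adjusted p = 0.56) without MK3 replicate 1, 1.29 (adjusted p = 1.7e-04) without MK3 replicate 2 and 0.45 (adjusted p = 0.0381) without MK4 replicate 1. The cytoskeletal list was shifted down (median -0.14, camera adjusted p = 0.0179, adjusted p = 0.70 with an estimated correlation). Its median was -0.35 (adjusted p = 5.1e-09) and -0.034 (adjusted p = 0.53) without MK3 replicates 1 and 2, and -0.27 (adjusted p = 0.00429) and -0.023 (adjusted p = 0.34) without MK4 replicates 1 and 2. It was -0.078 (adjusted p = 0.19) and -0.26 (adjusted p = 0.0658) under quantile normalization and a common median. Neutrophil markers (median -0.21, camera adjusted p = 0.0177, adjusted p = 0.70 with an estimated correlation) and mast cell markers (median -0.29, camera adjusted p = 0.0179, adjusted p = 0.59 with an estimated correlation) were shifted down. The neutrophil median was -0.057 (adjusted p = 0.0479) and -0.40 (adjusted p = 0.0514) without MK3 replicates 1 and 2 and -0.37 (adjusted p = 0.0545) and -0.14 (adjusted p = 0.0522) without MK4 replicates 1 and 2. The call also ended under quantile normalization at -0.14 (adjusted p = 0.0861) and a common median at -0.33 (adjusted p = 0.0725). The mast cell median was 0.17 (adjusted p = 0.51) and -0.68 (adjusted p = 0.00237) without MK3 replicates 1 and 2 and -0.45 (adjusted p = 0.00323) and -0.068 (adjusted p = 0.33) without MK4 replicates 1 and 2. With 1 array left out, camera also called DNA replication at -0.21 (adjusted p = 0.0238), cholesterol synthesis at -0.27 (adjusted p = 0.00317) and erythroid markers at -0.26 (adjusted p = 0.0375) without MK3 replicate 1, alpha-granule genes at 0.41 (adjusted p = 4.2e-04), transcription factors at 0.15 (adjusted p = 0.0303), stem and progenitor genes at 0.34 (adjusted p = 0.0267) and cholesterol synthesis at 0.30 (adjusted p = 0.0336) without MK3 replicate 2, cholesterol synthesis at -0.46 (adjusted p = 5.8e-04) without MK4 replicate 1, ribosome biogenesis at 0.37 (adjusted p = 0.00285) and cholesterol synthesis at 0.54 (adjusted p = 0.00285) without MK4 replicate 2 and stem and progenitor genes at 0.14 (adjusted p = 0.0227) without MK6 replicate 3. The receptor list had a median of 0.20 (adjusted p = 0.0109) with the higher pseudocount and 0.19 (adjusted p = 0.026) under a common median. The cytoskeletal list missed the camera threshold at -0.11 (adjusted p = 0.088) with the stricter filter and -0.086 (adjusted p = 0.12) with the mean of a gene's probe sets. NF-E2 targets missed the camera threshold at 0.64 (adjusted p = 0.12) with the stricter filter. Mast cell markers missed the camera threshold at -0.29 (adjusted p = 0.0515) without MK6 replicates 2 and 3. Hepatocyte markers had a median of -1.03 (adjusted p = 2.5e-15) with the higher pseudocount. Other settings in which camera called further lists gave alpha-granule genes at 0.23 (adjusted p = 0.0155) under quantile normalization, stem and progenitor genes at 0.14 (adjusted p = 0.0323) with array weights, stem and progenitor genes at 0.14 (adjusted p = 0.0306) without MK6 replicates 2 and 3, and erythroid markers at -0.13 (adjusted p = 0.036) with no filter on low values. Median, mean and camera direction differed in sign for dense-granule genes (0.020, 0.037 and down), cholesterol synthesis (0.030, 0.041 and down) and lymphocyte markers (0.079, 0.040 and down), none of them called with no setting changed.

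From MK4 to MK6, the last step, 2 genes passed the test. Nqo1, a quinone reductase of the antioxidant response, rose from 6.89 ± 0.35 (SD, n = 2) to 9.17 ± 0.15 (SD, n = 3), by 2.27 ± 0.25 (adjusted p = 0.0101) in limma with Benjamini-Hochberg adjustment. Map11 fell from 7.46 ± 0.074 to 4.99 ± 0.12, by 2.47 ± 0.27 (adjusted p = 0.0101) log2 units, to signals below the filter on all 3 MK6 arrays. At an unadjusted p below 0.05 there were 459 higher and 521 lower genes. The counts of higher and lower genes were 0 and 0 without MK4 replicate 1, MK4 replicate 2 or MK6 replicate 2, which ended both calls. They were 25 and 91 without MK6 replicate 1, 1 and 4 without MK6 replicate 3, and 2 and 2 without either MK3 array. Without MK6 replicates 2 and 3 they were 0 and 0.

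All 11 lists that passed camera in this step were shifted down, a step in which the actin 3' to 5' ratio also differed, at 1.04 and 1.09 on the MK4 arrays against 1.33, 3.21 and 1.49 on the MK6 arrays. Neutrophil markers had a median of -0.997 (camera adjusted p = 2.0e-06, adjusted p = 0.49 with an estimated correlation). Elane lay at -3.995 and Mpo at -2.92, with 0 members called and 6 adjusted over the list alone. Their median was -1.53 (adjusted p = 9.3e-15) without MK6 replicate 1, -0.49 (adjusted p = 0.00391) without MK6 replicate 2 and -0.021 (adjusted p = 0.54) without MK6 replicates 2 and 3. Hepatocyte markers had a median of -1.12 (camera adjusted p = 1.2e-04, adjusted p = 0.49 with an estimated correlation), and -0.43 (adjusted p = 0.0109) without MK4 replicate 2. Macrophage markers had a median of -0.59 (camera adjusted p = 0.00102, adjusted p = 0.49 with an estimated correlation), with -0.89 (adjusted p = 1.7e-06) and -0.078 (adjusted p = 0.25) without MK4 replicates 1 and 2. Endoplasmic reticulum genes had a median of -0.45 (camera adjusted p = 4.3e-05, adjusted p = 0.45 with an estimated correlation), with -0.34 (adjusted p = 0.00696) without MK6 replicates 2 and 3. Receptors had a median of -0.58 (camera adjusted p = 4.2e-05, adjusted p = 0.49 with an estimated correlation), with -0.34 (adjusted p = 0.00212) without MK4 replicate 1 and -0.35 (adjusted p = 0.0502) without MK6 replicates 2 and 3.

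Replication and mitosis genes also lay lower in MK6 than in MK4, and both calls rested on MK6 replicate 3. For DNA replication (median -0.47, camera adjusted p = 2.0e-06, adjusted p = 0.49 with an estimated correlation) the median was -0.059 (adjusted p = 0.27) without MK6 replicate 3 and -0.76 (adjusted p = 1.3e-09) without MK6 replicate 1. For mitosis (median -0.58, camera adjusted p = 5.0e-06, adjusted p = 0.49 with an estimated correlation) it was -0.15 (adjusted p = 0.33) without MK6 replicate 3 and -0.33 (adjusted p = 0.00184) without MK4 replicate 1. Without MK6 replicates 2 and 3 these medians were 0.018 (adjusted p = 0.92) and 0.19 (adjusted p = 0.0225), both positive. Ribosome biogenesis (median -0.34, camera adjusted p = 0.00592, adjusted p = 0.49 with an estimated correlation) had medians of -0.17 (adjusted p = 0.48) and -0.59 (adjusted p = 3.6e-05) without MK4 replicates 1 and 2. These were -0.54 (adjusted p = 0.00364) and -0.13 (adjusted p = 0.33) without MK6 replicates 1 and 3, and -0.13 (adjusted p = 0.67) without MK6 replicates 2 and 3. Cholesterol synthesis (median -0.44, camera adjusted p = 7.7e-05, adjusted p = 0.49 with an estimated correlation) had medians of -0.14 (adjusted p = 0.42) and -0.92 (adjusted p = 2.5e-10) without MK4 replicates 1 and 2, and -0.16 (adjusted p = 0.31) without MK6 replicates 2 and 3. The cytoskeletal list (median -0.25, camera adjusted p = 4.2e-04, adjusted p = 0.49 with an estimated correlation) had medians of -0.036 (adjusted p = 0.0177) and -0.54 (adjusted p = 1.5e-05) without MK6 replicates 3 and 1, and 0.065 (adjusted p = 0.90) without replicates 2 and 3. Transcription factors (median -0.13, camera adjusted p = 0.0217, adjusted p = 0.49 with an estimated correlation) had medians of -0.15 (adjusted p = 0.19) and -0.36 (adjusted p = 0.0152) without MK4 replicates 1 and 2. They were -0.089 (adjusted p = 0.33) and -0.25 (adjusted p = 0.00455) without MK6 replicates 3 and 1, and 0.093 (adjusted p = 0.92) without MK6 replicates 2 and 3. With 1 array left out, camera also called mitochondrial respiration at 0.26 (adjusted p = 0.0445) without MK6 replicate 3 and alpha-granule genes at -0.34 (adjusted p = 0.0204) without MK6 replicate 1. The receptor list had a median of -0.30 (adjusted p = 0.0079) with the beta-actin ratio as a covariate. The cytoskeletal list missed the camera threshold at -0.22 (adjusted p = 0.16) with the beta-actin ratio as a covariate, and had a median of -0.65 (adjusted p = 3.4e-06) with the mean of a gene's probe sets and -0.39 (adjusted p = 1.0e-04) without probe sets shared within or across gene families. Transcription factors missed the camera threshold at -0.15 (adjusted p = 0.0725) with array weights, and had a median of -0.20 (adjusted p = 0.0275) under a common median, -0.31 (adjusted p = 0.00316) with the mean of a gene's probe sets and -0.21 (adjusted p = 0.0402) with the beta-actin ratio as a covariate. DNA replication had a median of -0.17 (adjusted p = 0.00298) with array weights. Mitosis genes had a median of -0.36 (adjusted p = 7.2e-06) with the higher pseudocount. Ribosome biogenesis missed the camera threshold at -0.23 (adjusted p = 0.18) with array weights, and had a median of -0.53 (adjusted p = 1.6e-04) with the beta-actin ratio as a covariate. Cholesterol synthesis had a median of -0.23 (adjusted p = 0.0402) with the beta-actin ratio as a covariate. Neutrophil markers missed the camera threshold at 0.070 (adjusted p = 0.92) with the beta-actin ratio as a covariate, and had a median of -1.76 (adjusted p = 1.3e-10) with array weights. Macrophage markers missed the camera threshold at -0.28 (adjusted p = 0.18) with the beta-actin ratio as a covariate. Hepatocyte markers had a median of -0.48 (adjusted p = 4.8e-04) with the higher pseudocount. Other settings in which camera called further lists gave alpha-granule genes at -0.40 (adjusted p = 0.0183) with array weights, mitochondrial respiration at 0.24 (adjusted p = 0.0185) and fibroblast and endothelial markers at -0.27 (adjusted p = 0.0446) without MK6 replicates 2 and 3, apoptosis regulators at -0.40 (adjusted p = 0.00424) with the mean of a gene's probe sets, and mast cell markers at -0.35 (adjusted p = 0.0141) with the stricter filter. Median, mean and camera direction differed in sign for eicosanoid synthesis (0.086, -0.12 and down) and mast cell markers (0.071, -0.29 and down), none of them called with no setting changed.

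Over the whole course, 262 genes differed among the 4 stages in the F test of limma with Benjamini-Hochberg adjustment. Of these, 70 had their highest mean at MKP, 95 at MK3, 4 at MK4 and 93 at MK6, against 27.2%, 16.4%, 12.3% and 44.1% of all tested genes. The lowest mean was at MKP for 93, at MK3 for 19, at MK4 for 5 and at MK6 for 145. Means increased at all 3 steps for 42 genes, such as Mmp12 with 4.56, 6.63, 7.33 and 9.61 at MKP, MK3, MK4 and MK6, and Srxn1 with 7.88, 8.57, 9.69 and 11.06. They decreased at all 3 steps for 43 genes. Ttr, with 5.70, 9.15, 5.43 and 4.40, and Lpl, with 8.25, 11.73, 9.72 and 9.66, were among those highest at MK3. The total was 4 without either MKP array, 9 without MK6 replicate 2, 147 without MK3 replicate 1, 172 without MK4 replicate 2 and 27 without MK6 replicates 2 and 3. The numbers by highest stage ranged over the alternatives from 0 to 574 for MKP, 2 to 399 for MK3, 0 to 115 for MK4 and 0 to 648 for MK6.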

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

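All of these results lie outside the comparisons above and were picked out after the data were seen, because control probe sets or probe sets without a single gene name differed between stages. Controls are given where a later stage differed from MKP by at least 1 log2 unit. The 3' control probe set for the endogenous pyruvate carboxylase lay above both MKP arrays on every MK4 and every MK6 array, by 1.03 and 1.05 log2 units. Its signals were below the pseudocount on both MKP arrays and below the filter on both MK4 and 2 of 3 MK6 arrays, so these sizes are uncertain. The control probe set named murine b1 lay 1.05 log2 units higher in MK6, also on every array, with all signals above the filter. The 3' control for the transferrin receptor lay lower on every MK6 array than on both MKP arrays (-1.35), with signals below the filter on all MK6 arrays. The 3' and 5' controls for 18S ribosomal RNA differed by 1.33 and 1.01 in MK6, lying above both MKP arrays on 2 of 3 MK6 arrays each, and their signals were below the filter on both MKP arrays and on 1 and 3 of the MK6 arrays. Of the 2246 probe sets with several gene names or none, 1354 were above the signal filter, and 104 of these differed between MK6 and MKP in limma with Benjamini-Hochberg adjustment, 42 higher and 62 lower. Between MK6 and MK4, 1 of them passed, lower in MK6.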

How the results depend on the processing

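The settings that left out MK6 replicates 2 and 3 or used the beta-actin ratio were chosen after the data were seen. The counts of genes, with no setting changed, were 259, 276, 5, 0, 0, 1, 1, 1 and 262 in the order MK6 against MKP, MK3 against MKP, MK4 against MK3, MK6 against MK4 (each higher, then lower) and the F test. Settings that moved a count by over 1.5 times follow. With the pseudocount at the 5th percentile there were 0 lower in MK4 than MK3. With the pseudocount at the 50th percentile there were 15 higher in MK3 than MKP and 2 lower in MK3 than MKP. With no filter on low values there were 143 past the F test. With the filter at the 60th percentile there were 0 lower in MK4 than MK3. Under quantile normalization there were 146 past the F test. Under scaling to the same median there were 157 higher in MK6 than MKP and 0 higher in MK6 than MK4. With the mean of a gene's probe sets there were 1 lower in MK3 than MKP and 2 lower in MK6 than MK4. Leaving out probe sets shared within or across gene families there were 1 lower in MK3 than MKP. Testing every probe set by itself there were 620 lower in MK6 than MKP, 9 higher in MK3 than MKP, 2 lower in MK3 than MKP, 2 lower in MK4 than MK3 and 3 lower in MK6 than MK4. Without the intensity trend there were 180 lower in MK6 than MKP, 1 lower in MK3 than MKP and 101 past the F test. With array weights there were 1378 higher in MK6 than MKP, 1202 lower in MK6 than MKP, 158 higher in MK3 than MKP, 39 lower in MK3 than MKP, 172 higher in MK6 than MK4, 346 lower in MK6 than MK4 and 1736 past the F test. Fitting only the arrays of the 2 stages there were 179 lower in MK6 than MKP, 172 higher in MK3 than MKP, 36 lower in MK3 than MKP, 2 higher in MK6 than MK4 and 0 lower in MK6 than MK4. Leaving out MK6 replicates 2 and 3 there were 20 higher in MK6 than MKP, 29 lower in MK6 than MKP, 48 higher in MK3 than MKP, 10 lower in MK3 than MKP, 1 higher in MK4 than MK3, 3 lower in MK4 than MK3, 0 higher in MK6 than MK4, 0 lower in MK6 than MK4 and 27 past the F test. With the beta-actin ratio as a covariate there were 0 higher in MK6 than MKP, 0 lower in MK6 than MKP, 0 higher in MK6 than MK4, 0 lower in MK6 than MK4 and 2 past the F test. With each array left out in turn the counts ran from 3 to 561 genes higher in MK6 than MKP, 0 to 526 genes lower in MK6 than MKP, 0 to 77 genes higher in MK3 than MKP, 0 to 18 genes lower in MK3 than MKP, 0 to 1 genes higher in MK4 than MK3, 0 to 1 genes lower in MK4 than MK3, 0 to 25 genes higher in MK6 than MK4, 0 to 91 genes lower in MK6 than MK4 and 4 to 386 genes past the F test, where an arm left with 1 array is assumed to vary like the other stages. Other counts stayed within 1.5 times. The cause of these changes was not tested.

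All 1469 values of the 64 called results of named genes kept their sign over 23 settings. Other variance models or fewer arrays could not turn it, as the groups of called genes do not overlap. Tests of single probe sets, not among the 23, gave the opposite sign for Srxn1, Mcm3 and Tln1, without passing. Of all 2609 values of named genes, 2150 kept direction and side of the threshold, 356 lost a call, 93 gained one and 10 turned sign without a call. Of 2024 list values, 1759 stayed, 142 lost a call, 42 gained one, 73 turned without a call and 8 turned with a call in at least 1 of the settings compared. In MK4 against MK3 these were the receptors (-0.18 to 0.97 over the arrays left out, -0.18 without MK3 replicate 1), the cytoskeletal list (-0.35 to -0.023, -0.034 without MK3 replicate 2, where the camera direction turned) and cholesterol synthesis (-0.46 to 0.54, 0.30 without MK3 replicate 2 and 0.54 without MK4 replicate 2). In MK6 against MK4 they were mitochondrial respiration (-0.13 to 0.26, with 0.26 without MK6 replicate 3) and, without MK6 replicates 2 and 3, mitochondrial respiration at 0.24, DNA replication at 0.018 and mitosis at 0.19; the cause was not tested. The lists were not run with robust variance, with only the arrays of the 2 stages or with every probe set by itself. No paired analysis was possible because the labels number only 2 MK6 arrays, so the stages share no replicate numbers. No detection calls were used, so how far signals stand above background is known only through the filter, which the dimmest genes pass on few arrays.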

Other observations

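The 8 lists described first were chosen after the main results were seen, and so were the genes named from them. Their camera p was adjusted over these 8 lists alone. Genes that interferons induce lay higher at MK3 than at MKP, with Ifit1 at 1.90 ± 0.37, Rsad2 at 2.65 ± 0.55, Mx1 at 2.17 ± 0.46 and Ifit3 at 2.75 ± 0.60, and 0 of 11 passing over all genes in limma (10 adjusted over the list alone). The list's median was 1.72 (camera adjusted p = 5.3e-14, adjusted p = 0.15 with an estimated correlation). They lay lower at MK4 than at MK3 (median -0.94, camera adjusted p = 6.9e-13, adjusted p = 0.32 with an estimated correlation) and at MK6 than at MK4 (median -1.16, camera adjusted p = 4.3e-08, adjusted p = 0.23 with an estimated correlation). The 2 MK4 arrays differed here, since these medians were -0.26 and -1.88 without MK4 replicate 1 and -1.59 and -0.39 without MK4 replicate 2. The mean log2 signal of this list was 7.71 and 7.75 on the MKP arrays, 9.61 and 9.42 on the MK3 arrays and 7.73 and 9.18 on the MK4 arrays. The macrophage markers stood at 8.94 and 8.86, 10.71 and 9.93, and 9.27 and 10.08 on the same arrays, also higher on MK4 replicate 2 than on replicate 1. Lysosome genes such as Hexa (1.27 ± 0.27), Lipa (1.51 ± 0.38) and Ctsb (1.30 ± 0.39) were also higher as a set at MK3 (median 0.96, camera adjusted p = 5.4e-10, adjusted p = 0.17 with an estimated correlation). In limma 0 of 16 passed and 8 adjusted over the list alone, and the median was 0.55 without MK3 replicate 1. The lysosome list had a mean log2 signal of 9.78 and 9.76 on the MKP arrays, 10.95 and 10.31 on the MK3 arrays and 9.93 and 10.49 on the MK4 arrays. These follow the same order within MK3 and within MK4 as the macrophage markers. The list was shifted down from MK3 to MK4 (median -0.47, camera adjusted p = 3.5e-06, adjusted p = 0.32 with an estimated correlation), a call that ended without MK3 replicate 1 at -0.16 (adjusted p = 0.15) and without MK4 replicate 1 at -0.20 (adjusted p = 0.14). It stood at -0.74 (adjusted p = 1.3e-07) without MK3 replicate 2 and -0.72 (adjusted p = 4.4e-10) without MK4 replicate 2. MK6 lay above MKP (median 0.73, camera adjusted p = 0.0042, adjusted p = 0.81 with an estimated correlation), with 0.46 (adjusted p = 0.0194) without MK6 replicate 3 and 0.36 (adjusted p = 0.00231) without MK6 replicates 2 and 3. Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 18 of 18 differences negative at MK3 (median -0.33, camera adjusted p = 0.00431, adjusted p = 0.62 with an estimated correlation). This call ended without MK3 replicate 1 at -0.15 (adjusted p = 0.24). At MK4 against MK3, 18 of 18 differences were positive (median 0.30, camera adjusted p = 5.4e-04, adjusted p = 0.50 with an estimated correlation), a call that also ended without MK3 replicate 1, at 0.16 (adjusted p = 0.26). In MK6 against MKP the median was -0.24 (camera adjusted p = 0.0432, adjusted p = 0.81 with an estimated correlation). There it missed the threshold without MKP replicate 1 at -0.13 (adjusted p = 0.13), without MK6 replicate 3 at -0.039 (adjusted p = 0.59), under quantile normalization at -0.21 (adjusted p = 0.0788) and under a common median at -0.36 (adjusted p = 0.0607). It was -0.0085 (adjusted p = 0.88) without MK6 replicates 2 and 3. From MK4 to MK6 it was -0.15 (camera adjusted p = 0.00778, adjusted p = 0.55 with an estimated correlation), with -0.089 (adjusted p = 0.0672) without MK4 replicate 1 and 0.091 (adjusted p = 0.81) without MK6 replicate 3.

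Of the 17 measured antioxidant response genes, 8 rose between MKP and MK6, 1 fell and 8 did not pass. The biliverdin reductase Blvrb (2.30 ± 0.27), the epoxide hydrolase Ephx1 (2.11 ± 0.27), catalase Cat (2.01 ± 0.26) and the glutathione synthesis gene Gclm (1.81 ± 0.29) were among those that rose, and Gsr fell (-1.19 ± 0.31). Adjusted over the list alone 9 rose and 1 fell (median 0.83, camera adjusted p = 4.6e-05, adjusted p = 0.0362 with an estimated correlation). Adjusted over all 30 lists the camera call held (adjusted p = 3.4e-05), but with an estimated correlation it did not pass (adjusted p = 0.14). The list also lay higher in MK6 than in MK4 (median 0.56, camera adjusted p = 3.4e-04, adjusted p = 0.0727 with an estimated correlation), and leaving out any 1 array ended neither call. At MK3 it lay above MKP (median 0.34, camera adjusted p = 0.0133, adjusted p = 0.15 with an estimated correlation), a call that ended without MKP replicate 2 at 0.27 (adjusted p = 0.0567) and without MK3 replicate 1 at 0.045 (adjusted p = 0.0705). The glycolysis genes Pfkl (-1.82 ± 0.31) and Tpi1 (-0.96 ± 0.25) fell, and that list had a median of -0.29 (camera adjusted p = 0.0216, adjusted p = 0.70 with an estimated correlation). Its call ended without MKP replicate 1 at -0.17 (adjusted p = 0.0759), without MK6 replicate 2 at -0.20 (adjusted p = 0.0642) and without MK6 replicates 2 and 3 at -0.23 (adjusted p = 0.20). Glycolysis genes were also shifted down from MK4 to MK6 (median -0.27, camera adjusted p = 2.2e-04, adjusted p = 0.23 with an estimated correlation), with -0.40 (adjusted p = 6.3e-04) without MK4 replicate 1. Of the hypoxia-regulated genes Vegfa rose (1.57 ± 0.39) and Egln1 fell (-2.10 ± 0.48), and the list's median was -0.077 (camera adjusted p = 0.56, adjusted p = 0.86 with an estimated correlation). From MK4 to MK6 that list was shifted down (median -0.26, camera adjusted p = 0.0191, adjusted p = 0.38 with an estimated correlation). This call ended without MK4 replicate 2 at -0.053 (adjusted p = 0.56), MK6 replicate 2 at -0.11 (adjusted p = 0.13) or MK6 replicates 2 and 3 at -0.17 (adjusted p = 0.40) and with the beta-actin ratio as a covariate at -0.012 (adjusted p = 0.75), and the median was -0.50 (adjusted p = 6.3e-04) without MK4 replicate 1. The second hepatocyte list was shifted down from MK3 to MK4 (median -0.39, camera adjusted p = 1.1e-04, adjusted p = 0.32 with an estimated correlation), a call that ended without MK4 replicate 1 at -0.25 (adjusted p = 0.0558), with -0.59 (adjusted p = 0.00144) without MK3 replicate 2. From MK4 to MK6 it was lower too (median -0.14, camera adjusted p = 0.00955, adjusted p = 0.38 with an estimated correlation), but -0.060 (adjusted p = 0.32) without MK4 replicate 2 and 0.070 (adjusted p = 0.12) without MK6 replicate 1. It was -0.37 without MK6 replicate 3, -0.48 without replicates 2 and 3, -0.36 with the actin ratio as a covariate and -0.22 under quantile normalization, all called. Proteasome genes had a median of 0.14 and a mean of 0.0080 with camera down (adjusted p = 0.76, adjusted p = 0.92 with an estimated correlation), and 0 of 18 passed in limma.

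The 3 patterns that follow were weighed with 6 tests, and those on the scaling of the arrays, on the share of the main cell type and on Srxn1 and Nqo1 in MK6 replicate 1 were chosen after the results they measure were seen. The first pattern is the 535 genes that differ between MK6 and MKP. Under both other scalings 60.4% of them were called, which argues against the choice among these scalings as the whole cause. All set a common level, so its effect was not tested. RNA degradation in MK6 replicates 2 and 3 stays open, though the Gapdh ratio was 0.996 on replicate 3. As all 3 MK6 arrays had the highest actin ratios, degradation cannot be told from the stage. Genes picked for a difference over 2 log2 units between those 2 arrays and 1 MKP array kept a median of 50.3% or 49.6% of it, by the MKP array used for picking, in MK6 replicate 1 against the other MKP array, a mean of 49.9% beside the bounds of 25% and 50% set beforehand, with 92.1% to 93.4% in the same direction. With the actin ratio as a covariate the calls ended, at 4 residual degrees of freedom. The called genes' median standard error went from 0.303 to 0.417 and their median absolute difference from 1.53 to 1.33. All 535 kept their sign. The ratio was highest in MK6, so this decides nothing.

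The second pattern is the hepatocyte transcripts at MK3, where Afp reached 10.58, Alb 10.02 and Ttr 9.15 against 8.21, 7.75 and 5.70 at MKP. Of 8 measured members, none on another list, 7 lay higher and Hnf4a lower. A lower share of the main cell type would raise the markers of every other type alike. The neutrophil list's median of -0.46 cannot decide this, as that list also lay lower at each later step. The remaining marker lists had medians of 0.17 to 1.54. RNA from hepatocytes is a candidate source, since fetal liver cultures could carry it, although the CD41 sort would remove intact cells. A further hepatocyte list, predicted before its values were seen to lie above 0.5, had a median of 0.70 over 16 genes (camera adjusted p = 1.1e-05, adjusted p = 0.17 with an estimated correlation), or 0.54 over 17 under the first matching of symbols, which was corrected after that value was seen, with 7 rises and 1 fall adjusted over the list alone. The labels do not give tissue of origin per array, so whether MK3 differs in it stays open.

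The third pattern is the rise of Srxn1 (3.18) and Nqo1 (2.85) in MK6 against MKP, both targets of the antioxidant response. MK6 replicate 1 shared the rise (3.02 for the smaller difference from the MKP mean). Its actin ratio was 1.33, so RNA degradation in all 3 MK6 arrays stays open. Further antioxidant genes, not looked at before, had a median 0.710 log2 units above that of all genes, so a broader antioxidant response in maturing cells is a candidate explanation, as a hypothesis found and tested on the same arrays. Over all 30 lists the set's adjusted p = 0.14 with an estimated correlation did not pass, and its member Gsr fell. The lower values of the other Srxn1 probe sets and the longer time of MK6 in culture, which no comparison here separates from maturation, remain open.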
